A study of Mus musculus with 4 samples.

How the data were processed

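Single-cell RNA was measured in small intestinal crypt cells of 4 samples, 2 Fed and 2 Fasted for 24 h, per the labels. The deposited matrices hold raw counts of UMIs per gene and barcode, as whole numbers with no normalization. Per the submitters' processing notes, Cell Ranger and Seurat were used with the genome build mm10. Their versions and roles are not given in the sources used here. The deposited barcodes had been filtered, as no barcode had fewer than 500 UMIs. Both feature lists were identical and held 32287 entries, of which 32158 matched GENCODE vM21 by gene ID. Gene positions are from that annotation, on mm10, counted from 1.

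Cells with at least 500 genes and at most 25% of UMIs on mitochondrially encoded genes were kept. Of the barcodes left out, 1571 Fed and 3969 Fasted had fewer genes, and 38 Fed and 353 Fasted had a higher mitochondrial share. Doublets were called in each matrix with Scrublet in scanpy 1.11.5. It called 2 of 3187 Fed cells and 6 of 4577 Fasted cells, too few for this loading, so doublet removal has not worked here, and mixed cells may remain in every class.

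Counts of both matrices were normalised to a total of 10000 per cell and log-transformed. Clustering used 2000 variable genes, 30 principal components, 15 neighbours and the Leiden algorithm at resolution 1.0 (leidenalg 0.10.2) without integration. Clusters were named from marker genes fixed before the data were examined. A cluster took the class with the highest mean log2 ratio over its markers, from CPM with a pseudocount of 20, if at least 3 markers were 2-fold up and no other class had more markers among the 10 leading genes. A cluster with a median depth more than 3-fold below that of all cells of its group needed a marker among them as well, and in the main clustering no cluster went unnamed by this.

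UMIs were summed over the cells of a class and scaled to the class total as CPM. The summed depth was 16651334 UMIs over kept Fed and 45841521 over kept Fasted cells. A class entered with at least 50 kept cells in each group. Stem and goblet cells were added after the data were seen, with a minimum of 20 cells in each group. The log2 ratio of Fasted over Fed has the exact conditional binomial 95% interval for 2 Poisson counts, and shares of cells have exact Clopper-Pearson 95% intervals. A group at 0 counts was set to a floor of 3 counts over the group. Free RNA was not removed from the counts.

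Genes are named by a rule fixed before the data were examined. It takes genes with at least 100 UMIs in the class, without predicted gene models, mitochondrial, ribosomal, immunoglobulin and T cell receptor genes or markers of another class. The gene's CPM must reach 25% of its highest class. Ranked by the interval's bound nearest 0, 10 genes in each direction are named in stem cells and in the epithelial sum, and 5 in other classes. In each list, up to 4 members of the highest mean CPM and 2 of the largest ratio are named besides. Some genes that the rule picks are not reported here.

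Gene lists, 28 in all, were fixed before the data were examined. They cover fasting and PPAR targets, fatty acid synthesis, cholesterol, glycolysis, gluconeogenesis, Atf4 targets, intestinal stem cell genes, Wnt targets, regeneration, YAP and TAZ targets, p53 targets, S phase, G2 and M phase, MHC class II, interferon, antimicrobial genes, the IL-22 and Stat3 response, short-chain fatty acid receptors, acyl-CoA enzymes, enterocyte maturation, the nuclear respiratory chain, mitochondrially encoded transcripts, dissociation, heat shock, the unfolded protein response, autophagy, the circadian clock and apoptosis. A list's value is the median log2 ratio of members with at least 50 UMIs. Its counting interval comes from 1000 Poisson draws, and its percentile from 10000 random lists drawn from 20 bins of mean expression.

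The ratio and its interval were tested on simulated data with 200 changed genes. The simulated counts were Poisson draws, as the interval assumes, without variation between cells or free RNA. The simulation thus checks the calculation and not how well the intervals hold for these data. In the simulation of cycling progenitors, with 8047 genes, intervals held the true value for 95.7% of unchanged genes, and 97.8% of 2-fold and 100.0% of 4-fold changes had intervals excluding 0. In the simulation of stem cells, with 9288 genes, 71.6% of 2-fold changes did.

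Alternatives set before the data were examined were a stricter cell filter (1000 genes, 10% mitochondrial), every barcode, doublets kept, genes scaled within each matrix, resolutions 0.5 and 2.0, median-of-ratios size factors, totals without mitochondrial and the 20 most abundant genes, the mean of each cell's CPM, cells thinned to 2000 UMIs, other UMI minimums per gene (none and 300), lists without cell type markers, and classes weighted by their share over both groups for the epithelial sum. Added after the data were seen were cells of 8000 UMIs or more, the deepest cluster of a class, removal of the highest 5% of doublet scores, unnamed epithelial clusters included, and clustering without genes that were 2-fold apart between the groups. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.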

Results

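Small intestinal crypts of male C57BL/6J mice that had been fed or fasted for 24 h were profiled by droplet single-cell RNA sequencing with a 10x Genomics 5' library kit. The labels describe 4 samples, 2 Fed and 2 Fasted. The Fed mice were 9 and 9 weeks old and the Fasted mice 10 and 11 weeks, so age and diet group could not be separated. The data hold 1 count matrix per group, and every barcode carries the same suffix, so that a cell could not be assigned to 1 of the 2 samples of its group. Each group was therefore treated as 1 sample without replicates. No test between groups was possible, and every interval below covers counting error only, not differences between mice or preparations. Intervals of ratios treat UMIs as independent and leave out variation between cells. They are therefore too narrow where few cells were summed, as in the 24 Fed stem cells.

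The Fed matrix held 4796 barcodes with 18727803 unique molecular identifiers (UMIs), and the Fasted matrix held 8899 barcodes with 52762113 UMIs. After filtering, 3185 Fed cells and 4571 Fasted cells were kept. Median depth was 2492 UMIs and 1100 genes per kept Fed cell, against 4144 UMIs and 1415 genes per kept Fasted cell. The median share of UMIs on mitochondrially encoded genes was 0.487% in Fed and 3.73% in Fasted cells. The feature list includes entries for the reporters tdTomato and GFP. Neither had a UMI in any barcode, which allows a share of barcodes with a reporter UMI of up to 0.0626% in Fed and 0.0337% in Fasted.

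The cells of the 2 groups largely occupied separate clusters. The largest cluster, named enterocyte, held 1361 Fed cells and 2 Fasted cells, while another enterocyte cluster held 1 Fed and 691 Fasted cells. Among unnamed clusters, 1 held 35 Fed and 664 Fasted cells, and another 508 Fed and 3 Fasted cells. Of the cycling progenitors, 148 Fed and 49 Fasted cells lay in a cluster with a median of 3011 UMIs, and 47 Fed and 136 Fasted cells in one with a median of 32484 UMIs.

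Enterocytes made up 64.8% of kept Fed cells (2065 cells, exact 95% interval 63.1% to 66.5%) and 31.6% of kept Fasted cells (1446 cells, 30.3% to 33.0%). Stem cells made up 0.754% in Fed (24 cells, 0.483% to 1.12%) and 12.4% in Fasted (565 cells, 11.4% to 13.3%). Cycling progenitors made up 6.12% in Fed (195 cells, 5.31% to 7.01%) and 4.05% in Fasted (185 cells, 3.49% to 4.66%). T and NK cells made up 7.22% in Fed (230 cells, 6.35% to 8.18%) and 12.5% in Fasted (570 cells, 11.5% to 13.5%). Goblet cells numbered 26 in Fed and 194 in Fasted, Paneth cells 7 and 83, enteroendocrine cells 2 and 57, tuft cells 7 and 47, and erythroid cells 11 and 137. The shares of all of these classes were higher in Fasted. B and plasma cells went the other way, with 1.73% in Fed and 0.875% in Fasted. Differences in shares, that of stem cells included, cannot be told apart from differences between the preparations of the 2 matrices. No class was named for 17.6% of Fed and 26.7% of Fasted cells. The difference in the enterocyte share, -33.2 percentage points, depended on the clustering and changed sign at a Leiden resolution of 2.0 and with genes scaled within each matrix. The differences for cycling progenitors and for unnamed cells changed sign as well in some clusterings. When 1709 genes that differed between the groups within epithelial classes were left out of the clustering, enterocytes made up 68.5% of Fed and 43.0% of Fasted cells, and stem cells 2.23% and 17.0%. Depth differed along with these shares, with a median of 2172 UMIs in Fed and 1904.5 in Fasted enterocytes, and 28291.5 and 20809 in the stem cells.

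**Figure D1:**
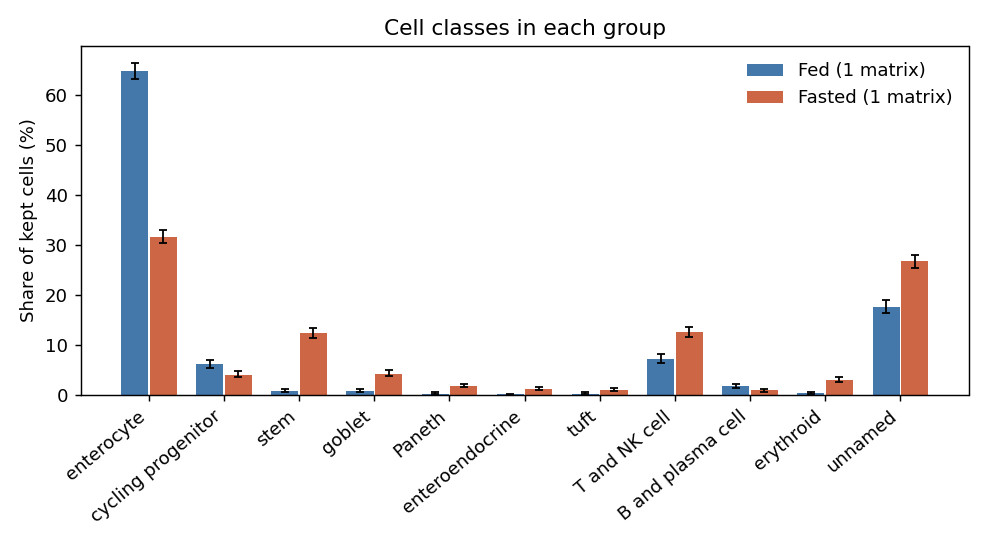
Share of kept cells (%) in each named cell class and in the unnamed clusters, for the Fed and the Fasted matrix; error bars are exact 95% binomial intervals. The enterocyte bar is at 64.8% for Fed and 31.6% for Fasted, and the stem bar at 0.754% and 12.4%.

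The comparison of Fasted with Fed asks how a 24 h fast relates to gene expression in the crypt, which the study's title connects with regeneration after damage. Within a class, UMIs were summed over cells and expressed as CPM (counts scaled to the class total), and ratios are given as log2 of Fasted over Fed. The median ratio over all genes with at least 50 UMIs was -0.09 in enterocytes, -0.18 in cycling progenitors, -0.13 in T and NK cells, -0.16 in stem cells, 0.09 in goblet cells and 0.05 in the sum over epithelial cells, and the ratios below include these shifts.

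In cycling progenitors, the list of fasting and PPAR targets, which holds genes of fatty acid oxidation and lipid handling, had a median log2 ratio of 1.18 (counting interval 1.05 to 1.30) over 32 measured members. Of these, 18 were at least 2-fold higher and 2 at least 2-fold lower in Fasted. Over the other settings the median ranged from 0.90 to 1.43. It lay at percentile 100 of 10000 random lists matched on expression. Cyp4a10 (ENSMUSG00000066072, mm10 chromosome 4, 115518264 to 115533649) had 0 UMIs in Fed and 394 in Fasted. It was 77.3-fold higher when Fed is set to a floor of 3 counts over the group (lower bound of the log2 ratio 5.97). Acot1 (ENSMUSG00000072949; chromosome 12, 84009490 to 84018371) had 120 UMIs in Fed and 2476 in Fasted, or 47.8 and 581 CPM, a log2 ratio of 3.60 (3.34 to 3.88). At least 1 Acot1 UMI was found in 17.4% of Fed and 91.4% of Fasted cycling progenitors, at median depths of 4839 and 27809 UMIs. In T and NK cells, used here to gauge free RNA, these shares were 1.30% and 4.74% at median depths of 2120 and 2145 UMIs. Creb3l3 was at 4.03 (3.38 to 4.78, but 1.53 with genes scaled within each matrix), Angptl4 at 3.85 (2.84 to 5.08) and Fabp1 at 3.29 (3.22 to 3.37).

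The genes most clearly lower in Fasted cycling progenitors were Gsdmc4, with 182 UMIs in Fed and 3 in Fasted (-6.69, -8.98 to -5.12), Rbp7 (-2.59), Atp5k (-2.06), Hist2h2bb (-2.26) and Hist1h2af (-2.16). Rbp7 was also among the leading genes of the cluster that held most Fed cycling progenitors, and Gsdmc4 led an unnamed cluster of Fed cells. The glycolysis list had a median of -0.81 (-0.93 to -0.71) over 11 members, at percentile 0.02, with Eno1 at -1.59, Gapdh at -1.37, Ldha at -1.23 and Pfkp at -1.82. The S phase list was lower (-0.70, 20 members, and -0.98 to -0.30 over the other settings). The G2 and M phase list was at -0.19 (21 members), with Mki67 at -0.03, but ranged from -1.36 when clustered without differing genes to 0.45 with genes scaled within each matrix. Cells of both groups entered this class by markers of cycling cells, so a small difference in the G2 and M phase list can follow from the naming. Of the S phase members, Mcm3 was at -1.11 and Rrm2 at -1.10. Lists of Wnt targets (0.61, 10 members), intestinal stem cell genes (0.33, 16 members) and the unfolded protein response (0.37, 12 members) were higher, with Ascl2 at 1.63, Sp5 at 1.41, Myc at 0.61 and Herpud1 at 1.25. In the deeper cycling progenitor cluster taken alone, however, the stem cell list was at -0.02 and the unfolded protein response list at -0.12. Ddit4 (2.33) and Txnip (1.56) were higher. The nuclear respiratory chain list was at -0.35 (21 members, Cycs at -1.24), the heat shock list at -0.53 (8 members), the interferon response list at -0.67 (10 members, Irf1 at -1.20) and the list of the tissue repair cytokine response to IL-22 and Stat3 at -0.84 (7 members, Nfkbiz at -2.25). Over the other settings, Wnt targets ranged from 0.14 to 1.06, the interferon response from -1.01 to -0.21 and the IL-22 and Stat3 list from -1.28 to -0.31. Mitochondrially encoded transcripts were at 0.57 (13 members, and 0.07 to 1.69 over the other settings), and genes of gluconeogenesis and the fasting hormone response at 0.32 (13 members, and 0.08 to 1.56 over the other settings).

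The circadian clock list was at -1.02 in cycling progenitors (-1.39 to -0.42, 5 members, at percentile 0.06), but at -0.036 without a minimum of UMIs and at -0.13 at resolution 2.0. Cholesterol synthesis and uptake was at -0.24 (-0.57 to -0.12, 16 members) and the antimicrobial list at 0.19 (0.02 to 0.40, 8 members), and both changed sign between settings. Several lists in cycling progenitors had counting intervals of the median that included 0. These were regeneration and fetal-like genes (-0.11, 7 members), YAP and TAZ targets (0.06, 4 members), p53 targets (0.06, 7 members, at percentile 92.0), acyl-CoA and histone acylation enzymes (-0.16, 30 members), autophagy and lysosome genes (-0.09, 12 members), fatty acid synthesis (-0.18, 7 members), enterocyte maturation and nutrient absorption (-0.23, 17 members, but 1.05 when clustered without differing genes), dissociation and immediate early genes (0.06, 7 members), and apoptosis genes (-0.04, 11 members). Of these, autophagy and lysosome genes ranged from -0.38 to 0.55 over the other settings. The list of Atf4 targets was at -0.34 (-0.55 to -0.11, 11 members), at percentile 12.2 of the random lists.

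Stem cells passed the minimum of 50 cells per group in Fasted only, and their comparison, from 24 Fed and 565 Fasted cells, was added after the data were seen. The list of fasting and PPAR targets had a median of 1.23 (0.99 to 1.32) over 33 members, 18 of them at least 2-fold higher and 0 at least 2-fold lower. Acot1 was at 2.96 (2.65 to 3.30), with 82 UMIs in Fed and 11273 in Fasted, and Fabp1 at 4.21 (3.97 to 4.46). Acot1 was among the leading genes of the stem cluster itself. In the clustering without genes that differed between the groups, which gave 71 Fed and 778 Fasted stem cells, the list median was 1.22 and Acot1 was at 3.40. The nuclear respiratory chain was at -0.41 (21 members). Also higher were Creb3l3 (3.34, from 9 Fed UMIs, and 1.16 with cells thinned to 2000 UMIs), Angptl4 (3.24), Mt2 (1.87) and Mt1 (1.69). Few Fed counts stood behind Cyp4a10 (2 UMIs, 4.46, 2.60 to 7.50, and -0.28 with cells thinned to 2000 UMIs), Pdk4 (3 UMIs, 3.26, 1.70 to 5.54) and Me1 (1 UMI, 4.18, 1.70 to 9.49, and 0.97 when clustered without differing genes). Acta1 had 0 UMIs in Fed and 355 in Fasted, 6.72-fold higher against the floor of 3 counts (lower bound of the log2 ratio 2.44). In 24 Fed cells thinned to 2000 UMIs, a gene can fall to 0 UMIs and be set to that floor. The thinned values of Creb3l3 and Cyp4a10 are therefore not read as a loss of the difference. Lower in Fasted were Clca4b (-3.81), Dynlt1f (-2.63), Slc39a4 (-2.34), Cenpw (-2.10), Atp5k (-2.09), Clca3b (-1.84), Ndufb1-ps (-1.68), Erh (-1.60), Cps1 (-1.56) and Olfm4 (-1.46, -1.52 to -1.41).

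Several other lists were lower in Fasted stem cells. The G2 and M phase list was at -1.21 (-1.39 to -0.90, 16 members, 11 of them at least 2-fold lower), with Mki67 at -1.57 and Ccnb2 at -1.62. Over the other settings this list ranged from -1.88 to -1.04. However, a cluster led by Olfm4, with stem as its second class, was named cycling progenitor (47 Fed and 136 Fasted cells). Whether the boundary between these classes sets the G2 and M phase value in the 24 Fed stem cells was not tested. The S phase list was at -0.59 (20 members), cholesterol synthesis and uptake at -0.72 (17 members, Fdps at -1.37 and Idi1 at -1.32) and fatty acid synthesis at -0.73 (7 members). Under other settings the S phase list reached -0.086 and fatty acid synthesis -0.12. Glycolysis was at -0.25 (13 members), at percentile 34.2 of the random lists and so not set apart, although Gapdh was at -1.05 and Eno1 at -1.19. The intestinal stem cell list (-0.14, -0.27 to 0.14, 20 members), Wnt targets (0.49, -0.09 to 0.71, 13 members) and MHC class II presentation (-0.47, -1.62 to 0.21, 3 members) had counting intervals that included 0. Among their members, Ascl2 was at 0.80, Sp5 at 1.29 (but -0.49 with cells thinned to 2000 UMIs), Myc at 1.00 and Cd74 at -2.40 (-1.02 when clustered without differing genes). The thinned Sp5 value can be set by the floor for Fed as well. Stem cells of both groups were named by stem cell markers. A stem cell list median near 0 can therefore follow from the naming and is not read as a lack of change.

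**Figure D2:**
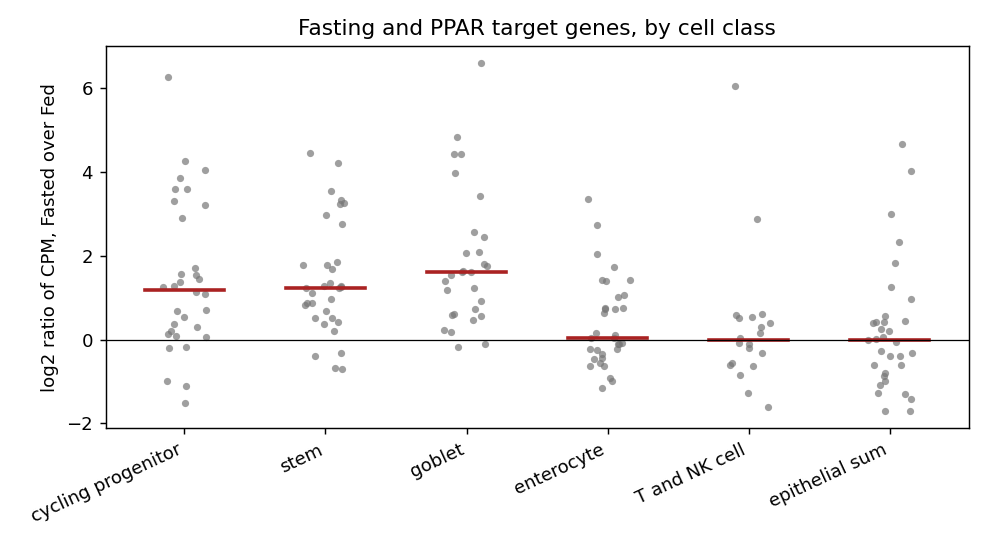
Log2 ratio of CPM, Fasted over Fed, for each measured member of the list of fasting and PPAR targets (grey points) by cell class, with the list median as a red line; a group at 0 counts is set to 3. Medians are 1.18 in cycling progenitors, 1.23 in stem cells and 1.60 in goblet cells (26 Fed and 194 Fasted cells), against 0.04 in enterocytes. The enterocyte median depended on which cells were counted and ranged from -0.08 to 0.59 over the other settings. Every setting that clustered the cells anew gave 0.29 to 0.59.

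In enterocytes, the list of fasting and PPAR targets had a median of 0.04 (-0.04 to 0.14) over 33 members, of which 9 were at least 2-fold higher and 1 at least 2-fold lower. This value rests on different clusters in each group and ranged from -0.08 to 0.59 over the other settings. Every setting that clustered the cells anew gave 0.29 to 0.59. The main value of 0.04 leaves out unnamed clusters led by the list members Cyp4a10 (35 Fed and 664 Fasted cells) and Acot1 (8 Fed and 481 Fasted cells). Fabp1 (-0.11) and Fabp2 (-0.23) changed sign between settings. The genes named as highest in Fasted were Clu, with 4 UMIs in Fed and 135 in Fasted (5.50, 4.11 to 7.39), Reg3b (3.83), Tfrc (3.83), Angptl4 (3.34) and Mt2 (3.13). Named as lowest were Fabp6 (-4.75, -4.86 to -4.64), Apol10a (-3.00), Cyp2c29 (-2.95) and S100g (-2.76). Apol10a was a leading gene of the largest, Fed enterocyte cluster. In the deepest enterocyte cluster, which held 83 Fed and 130 Fasted cells, Fabp6 was higher in Fasted (0.68) and Apol10a was at -0.27.

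The unfolded protein response list was at 1.27 in enterocytes (1.07 to 1.41, 13 members, 8 of them at least 2-fold higher), with Hspa5 at 1.53 and Hsp90b1 at 1.40. The interferon response list was at -0.87 (-1.03 to -0.76, 18 members), with Psmb8 at -1.75, Ifit1 at -1.64 and Isg15 at -0.93. Over the other settings this list ranged from -1.90 to -0.56, Ifit1 from -3.54 to -0.90 and Isg15 from -2.86 to -0.54. The circadian clock list was at -0.50 (12 members), with Nr1d1 and Dbp both at -1.67, glycolysis at -0.47 (13 members), with Gapdh at -1.60 and Eno1 at -1.34, dissociation and immediate early genes at -0.45 (13 members), with Atf3 at -2.34 and Jun at -1.37, and apoptosis genes at -0.36 (15 members). In the deepest enterocyte cluster alone, glycolysis was at -0.032, dissociation genes at -0.011 and apoptosis genes at -0.089, and with cells thinned to 2000 UMIs the circadian clock was at -0.022. At resolution 2.0 the unfolded protein response was at 0.41, Hspa5 at 0.47 and Hsp90b1 at 0.31. The direction of 5 lists depended on which cells were counted as enterocytes. These were enterocyte maturation and nutrient absorption (0.52, 26 members), gluconeogenesis and fasting hormone response (0.40, 18 members) with its member Pck1 (0.79), mitochondrially encoded transcripts (0.83, 13 members), short-chain fatty acid receptors and transporters (0.87, 5 members) and the nuclear respiratory chain (-0.42, 21 members). Apoa1 (1.95), G6pc (1.69) and Ddit4 (2.64) were higher under every setting that gave a value, but went down to 0.16, 0.46 and 1.45. The antimicrobial list was at 2.71 (8 members), and at 0.89 without a minimum of UMIs, with Lyz1 at 6.13 and Reg3g at 1.59 (0.37 with every barcode). Lyz1, a Paneth cell gene, had a UMI in 4.60% of Fed and 92.9% of Fasted enterocytes, and in 5.65% of Fed and 93.9% of Fasted T and NK cells, so the Lyz1 value is at the level of free RNA. The antimicrobial list was at 3.95 in T and NK cells, so free RNA may carry a part of the enterocyte list median too. Reg3b was at 7084 CPM in Fasted enterocytes and 93.9 CPM in Fasted T and NK cells.

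In T and NK cells, the list of cholesterol synthesis and uptake had a median of -1.88 (-2.06 to -1.58) over 15 members, of which 13 were at least 2-fold lower in Fasted and 0 higher, at percentile 0 of the random lists. Fdps (ENSMUSG00000059743; mm10 chromosome 3, 89093588 to 89101959) had 199 UMIs in Fed and 87 in Fasted, or 283 and 53.7 CPM, a log2 ratio of -2.40 (-2.78 to -2.02). Cyp51 was at -2.23 (-2.80 to -1.69) and Hmgcs1 at -1.88 (-2.24 to -1.51). Fatty acid synthesis was at -0.69 (6 members), with Fasn at -1.52 and Scd2 at -1.57. Asb2 was at -1.92. Higher in Fasted were Ddit4 (1.53, 1.19 to 1.88), Tsc22d3 (1.30), Txnip (1.27), Tigit (1.06) and Ccl5 (0.65). Under other settings Tigit went down to 0.62 and Ccl5 to 0.25. Glycolysis was at -0.34 (11 members), with Gapdh at -1.37 and Eno1 at -0.92, the nuclear respiratory chain at -0.17 (21 members), and the fasting and PPAR targets at -0.02 (-0.17 to 0.20, 20 members). Genes of gluconeogenesis and the fasting hormone response were at 0.22 (-0.08 to 0.61, 11 members). The antimicrobial list was at 3.95 (6 members, and 1.09 to 6.08 over the other settings), with Itln1 at 6.45 and Lyz1 at 6.08. Lyz1 is at the level of free RNA as above. Itln1 is a leading gene of the Paneth cluster. The Paneth cell gene Defa24 was at 138 CPM in Fed and 6630 CPM in Fasted T and NK cells. Free RNA may thus carry Itln1 and the list as well, and neither is read as expression by T and NK cells.

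**Figure D3:**
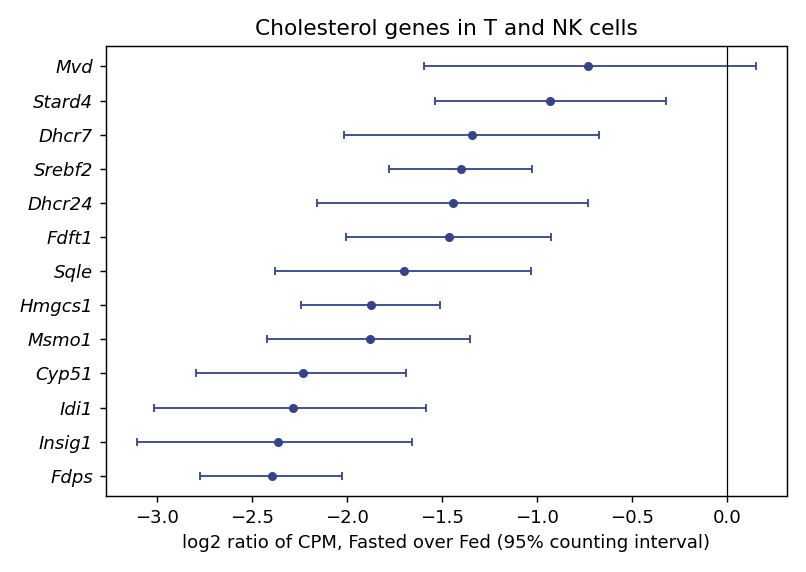
Log2 ratio of CPM, Fasted over Fed, for 13 of the 15 measured genes of cholesterol synthesis and uptake in T and NK cells; bars are exact 95% intervals for counting error. The median of the list is -1.88, and the interval of Mvd includes 0.

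The sum over all named epithelial cells (2326 Fed and 2577 Fasted) mixes changes within classes with their different shares. Acot1 was at 4.03, Ddit4 at 2.82, Mt2 at 2.62, Sema3c at 3.13, Sycn at 2.73, Gas6 at 2.47 and Ascl2 at 2.55. Angptl4 was 7.97-fold higher, and Adprhl1 had 2 UMIs in Fed and 100 in Fasted (4.38, 2.49 to 7.44). Named as lowest were Fabp6 (-6.42), Cyp2c29 (-4.63), Apol9b (-4.51), Tmprss15 (-4.39), Apol10a (-4.37), S100g (-4.36), Ccl24 (-4.30), Gsta2 (-4.09), Ugt2b5 (-3.86) and Gsta1 (-3.72). The list of fasting and PPAR targets was at -0.01 (-0.12 to 0.07, 33 members), and at 0.31 when each class was weighted by its share over both groups. The intestinal stem cell list was at 1.47 (20 members) and at -0.02 with that weighting, and enterocyte maturation at -0.88 (26 members) and 0.50. Glycolysis was at -1.34 (15 members, Gapdh at -2.53) and the interferon response at -1.45 (20 members). Over the other settings glycolysis ranged from -1.40 to -0.41, Gapdh from -2.58 to -1.57 and the interferon response from -1.51 to -0.76.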

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

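Tests of depth, free RNA, scaling, intestinal segment and clusters were chosen after the results were seen, and those of transcript length before in cycling progenitors and after in the other classes. None of the differences between cell classes was tested, as each group is 1 sample.

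Me1 and Olfm4 drew attention because their ratios had opposite directions in different classes. Me1 was higher in cycling progenitors (1.09) and stem cells (4.18, from 1 Fed UMI, and 0.97 when clustered without differing genes) and lower in enterocytes (-1.09). Olfm4 was higher in enterocytes (2.61, from 27 and 123 UMIs) and lower in stem cells (-1.46). Its stem cell value ranged from -1.49 to -0.83 over the other settings. In Fasted, Olfm4 was at 20.7 CPM in enterocytes, 40.8 CPM in T and NK cells and 1643 CPM in stem cells, so the enterocyte value is at the level of free RNA and is not read as expression by enterocytes.

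Signals in data outside the comparisons came from an unnamed cluster and from barcodes left out. A cluster led by Siglech, Bst2 and Irf8 held 1.58% of kept Fasted cells (72 cells, exact 95% interval 1.23% to 1.98%) and 0.283% of kept Fed cells (9 cells, 0.129% to 0.536%). Of all Fasted barcodes, 18.0% (1599 barcodes) had over 50% of their UMIs on mitochondrially encoded genes, against 6.82% (327) of Fed barcodes.

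The list of fasting and PPAR targets was higher in Fasted cycling progenitors, with a median of 1.18. With every cell thinned to 2000 UMIs it stayed at 1.00. Thinning gives cells equal weight but leaves the expected CPM of each cell unchanged. It cannot test whether deep and shallow cells differ in kind, so depth stays open. In the deeper cycling progenitor cluster alone (47 Fed and 136 Fasted cells) the list stayed within its counting interval, so the mix of the clusters was not the whole cause. T and NK cells showed a median of 6.32% of the CPM gain of the 21 members with intervals above 0, which argues against free RNA. Relative to genes of like transcript length the median was 1.33, which argues against a length bias. A response to fasting is a candidate explanation and was not tested apart from age or from the preparation of each matrix, which cannot be told apart from the diet group.

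The nuclear respiratory chain list was lower in Fasted enterocytes (-0.42), cycling progenitors (-0.35) and T and NK cells (-0.17), at percentiles 7.11, 9.93 and 9.91 that do not set it apart from random lists, and in stem cells (-0.41, percentile 1.46), but at 0.05 in goblet cells and at 0.030 in the deepest enterocyte cluster. Relative to genes of like transcript length, its median was -0.36 in enterocytes, which argues against length as the whole cause there. The medians of -0.15 in cycling progenitors, -0.14 in T and NK cells and -0.26 in stem cells leave a part of length open. With median-of-ratios size factors the list was at -0.33 in enterocytes and -0.25 in stem cells, which argues against scaling as the whole cause there, and at -0.18 in cycling progenitors, which leaves it open. In T and NK cells it was at -0.034, so scaling may explain the difference there, and a response to fasting stays open, untested.

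Fabp6, Apol10a, Cyp2c29 and S100g were among the lowest in Fasted enterocytes. In the deepest enterocyte cluster, which both groups share, Fabp6 was at 0.68 and Apol10a at -0.27, but when clustered without differing genes they were at -5.73 and -2.63, so the different clusters of the 2 groups are neither excluded nor shown as the cause. Cyp2c29 was at -5.34 and S100g at -4.93 in the deepest cluster, and at -4.23 and -3.56 when clustered without differing genes, which argues against the clusters as their whole cause. Markers of the distal intestine were higher in Fasted enterocytes (median 0.93, 9 of 9 members). Those of the proximal intestine were at -0.22, with 7 of 10 members lower. The proximal members that were higher were Cybrd1 (2.91), Slc11a2 (2.34) and Slc40a1 (0.50). Distal and proximal medians were 0.34 (4 members) and -0.08 (5 members) in cycling progenitors. In stem cells they were 1.01 (4 members) and -0.01 (6 members). The gap of 1.15 in enterocytes leaves a shift toward the distal end open for Cyp2c29 and S100g. Fabp6, known from the distal intestine and not among these markers, mostly went against such a shift. It was at -4.75 in all enterocytes and below 0 in every setting except the deepest cluster (0.68). In the epithelial sum it ranged from -7.30 to -3.51 over the other settings. The distal markers and Fabp6 thus disagree and do not settle the question, and fasting, age and preparation stay open, untested.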

How the results depend on the processing

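No paired analysis was possible because the 2 samples of a group share 1 matrix with 1 barcode suffix and cannot be told apart. For the same reason the planned tests with replicate libraries, a block for replicate number and the omission of 1 library at a time were not run. The settings with cells of 8000 UMIs or more, the deepest cluster, doublet scores, unnamed clusters and clustering without differing genes were chosen only after the results were seen. Over all settings, 941 gene values stayed within the interval of the main value, 632 moved outside it and 27 reversed. For list medians these numbers were 602, 334 and 36, and for shares of cells 12, 20 and 8. The cause was not tested for any of the changes below.

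Cholesterol synthesis and uptake in T and NK cells stayed within its interval under all 15 alternatives, between -2.02 and -1.74. The fasting and PPAR target list in cycling progenitors (1.18) stayed above 0 throughout. It moved to 1.43 with the mean of each cell's CPM, 1.36 with median-of-ratios size factors, 1.00 with cells thinned to 2000 UMIs, 1.34 with the stricter filter, 1.36 with doublets kept, 0.92 with genes scaled within each matrix, 0.90 at resolution 0.5, 1.36 at resolution 2.0 and 1.04 when clustered without differing genes.

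In enterocytes, the same list (0.04) moved to -0.078 with the mean of each cell's CPM, 0.21 in cells of 8000 UMIs or more, 0.40 in the deepest cluster, 0.51 with the stricter filter, 0.55 with every barcode, 0.59 with doublets kept, 0.51 with genes scaled within each matrix, 0.59 at resolution 0.5, 0.29 at resolution 2.0, 0.58 without the highest doublet scores and 0.59 when clustered without differing genes. Keeping doublets added only 2 Fed and 6 Fasted cells, but the cells were clustered anew. Enterocytes then numbered 2263 Fed and 2044 Fasted, against 2065 and 1446. A cluster led by Retsat and Cyp4a10 (28 Fed and 657 Fasted cells) was then named enterocyte, while the Cyp4a10-led cluster of the main clustering was unnamed. Values with doublets kept are therefore not read as effects of doublets. In the epithelial sum, the list of fasting and PPAR targets (-0.01) moved to 0.10, 0.11, 0.31 and 0.40 with the mean of each cell's CPM, thinned cells, weighted classes and unnamed clusters included. It moved to 0.43, 0.30, 0.31, 0.44, 0.39, 0.31, 0.36 and 0.33 with the stricter filter, every barcode, doublets kept, scaling within matrices, resolutions 0.5 and 2.0, doublet scores and clustering without differing genes.

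The enterocyte share (-33.2 percentage points) reversed to 1.21 with scaling within matrices and to 12.9 at resolution 2.0. It moved to -4.21 with the stricter filter, -29.6 with every barcode, -26.3 with doublets kept, -25.3 at resolution 0.5, -19.4 without the highest doublet scores and -25.6 when clustered without differing genes. The stem share (11.6 points) moved to 16.8, 6.04, 14.8, 8.40 and 14.8 with the stricter filter, every barcode, scaling within matrices, resolution 2.0 and clustering without differing genes. The cycling progenitor share reversed to 1.54 with the stricter filter and 3.93 at resolution 2.0. The unnamed share reversed to -28.5 with the stricter filter, -26.2 with scaling within matrices, -39.1 at resolution 2.0 and -3.54 without the highest doublet scores.

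Reversals in enterocytes were the most frequent. Maturation and nutrient absorption reversed to -0.33 in the deepest cluster and to -0.25, -0.056, -0.018, -0.74, -0.074, -0.22, -0.22 and -0.057 with the stricter filter, every barcode, doublets kept, scaling within matrices, resolutions 0.5 and 2.0, doublet scores and clustering without differing genes. With those settings apart from resolution 2.0, gluconeogenesis and fasting hormone response reversed to -0.31, -0.22, -0.18, -0.28, -0.24, -0.31 and -0.23, and Pck1 to -0.41, -0.39, -0.40, -0.45, -0.47, -0.54 and -0.41. Fabp1 reversed to 0.040 in cells of 8000 UMIs or more, 0.20 in the deepest cluster, and 0.51, 0.41, 0.44, 0.66, 0.42, 0.28, 0.45 and 0.47 with the stricter filter, every barcode, doublets kept, scaling within matrices, resolutions 0.5 and 2.0, doublet scores and clustering without differing genes. In the deepest cluster and at resolution 2.0, Fabp2 reversed to 0.25 and 0.34, mitochondrially encoded transcripts to -0.38 and -0.17, and short-chain fatty acid receptors and transporters to -0.22 and -0.18. The deepest cluster also reversed the nuclear respiratory chain (0.03) and Fabp6 (0.68).

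In cycling progenitors, the deepest cluster reversed the intestinal stem cell list (-0.025) and the unfolded protein response (-0.12), and clustering without differing genes reversed the stem cell list as well (-0.24). The G2 and M phase list and Top2a reversed to 0.45 and 0.33 with scaling within matrices and to 0.43 and 0.27 at resolution 0.5. Cholesterol synthesis and uptake reversed to 0.050 with the mean of each cell's CPM, 0.0077 with the stricter filter and 0.0052 with doublets kept, and the antimicrobial list to -0.12 without a minimum of UMIs, -0.49 without cell type markers and -0.34 with scaling within matrices. Olfm4 reversed to 0.78 with the mean of each cell's CPM, 0.59 with thinned cells and 0.23 at resolution 0.5. Thinned cells reversed Cyp4a10 (-0.28) and Sp5 (-0.49) in stem cells. In the epithelial sum, enterocyte maturation and nutrient absorption reversed to 0.16 with the mean of each cell's CPM, 0.016 with thinned cells and 0.50 with weighted classes, and the intestinal stem cell list to -0.021 with weighted classes.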

Other observations

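Genes known from mucous cells of the stomach were found almost wholly in 1 cell of the Fed matrix, and the list of these genes was made after their values were seen. Of 26384 UMIs of Gkn1, Gkn2, Tff1, Tff2, Muc5ac, Muc6, Psca and Anxa10 in kept Fed cells, 99.6% (26281 UMIs) lay in 1 cell of the goblet cluster. Kept Fasted cells held 61 such UMIs.

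In goblet cells, a class added after the data were seen, with 26 Fed and 194 Fasted cells, the list of fasting and PPAR targets had a median of 1.60 (1.30 to 1.77, 29 members). It was not run under the other settings, and 1 of the Fed cells is the cell with stomach genes.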
